A study of Mus musculus with 12 samples.

How the data were processed

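Single-nucleus RNA of frozen orthotopic KPC tumours was measured in 12 libraries, 1 for each of 2 lines and 6 treatments, with the 5-prime V(D)J chemistry of 10x Genomics per the submitters' processing notes. The values used are UMI count matrices deposited by the authors, with all barcodes kept and 32285 genes. The submitters' processing notes name Cell Ranger 6.1.2 and mm10, while the matrix headers name Cell Ranger 4. Whether intron reads were counted in every library is not stated in what was used here. Of the gene IDs, 32235 (99.85%) matched the annotation.

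Nuclei were called anew in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1). A barcode needed 500 UMIs and 3 times the median of the empty barcodes of ranks 45001 to 90000, with at most 20000 candidates per library. It was kept by an OrdMag rule (3000 barcodes ranked, percentile 99, divisor 10) or by a Monte Carlo test against the empty profile (10000 draws, Benjamini-Hochberg 0.01), and needed 300 genes and at most 5% mitochondrial UMIs. The empty median was 5 UMIs in KPC-4545 Control and TGFB-TRAP and up to 372 in the others, so the minimum per nucleus ran from 500 to 1116. In KPC-4545 Control and TGFB-TRAP the barcodes of ranks 20001 to 30000 had medians of 1084 and 590 UMIs, above their minimum of 500. Both reached the limit of 20000 candidates. In the other libraries that median lay below the minimum. Empty droplets among the nuclei of KPC-4545 Control and TGFB-TRAP are therefore not excluded. Scrublet in scanpy 1.11.5 marked 12 doublets at its automatic threshold, so the highest-scoring nuclei were removed at an expected 0.8% per 1000 nuclei instead, 578 of 22151 (2.61%), leaving 21573. It was not run in the 3 libraries of under 100 nuclei.

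Nuclei were clustered with 3000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 (anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0), giving 37 clusters, with 30 and 57 at resolutions of 0.5 and 2. No batch correction was applied. A cluster took a class name when at least 3 fixed markers were raised 2-fold over the median cluster, with 20 CPM added, 1 of them lay among its 100 leading genes, its 10 leading genes did not hold more markers of another class, and its median UMIs were at most 3 times that of its own libraries. Neither Alb nor Plin4 was to be among the 10, and clusters of low UMIs needed a marker there. Cluster 15 was clustered again (1000 genes, 10 components) into 9. The thresholds for names were set after the data were seen. The markers, the 20 gene lists, the groups, the tests and most alternatives were fixed before the data were examined.

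UMIs were summed per library and class, for classes with at least 20 nuclei (50 for all nuclei) in at least 8 libraries and 3 per line. Sums were tested in R 4.3.3 with edgeR 4.0.16 (TMM, filterByExpr, robust quasi-likelihood), with terms for line, anti-PD-1 and second agent, at a Benjamini-Hochberg adjusted p of 0.05, and with interaction terms in further fits. DESeq2 1.42.0 gave the alternative test. KPC-4545 alone was fitted for macrophage, T and endothelial nuclei, a choice made after the data were seen. Directions per pair were read with TMM factors, except with the intron trend removed; for 151 of 1585 named values, CPM without them, an alternative chosen after the data were seen, gave another number of pairs. The genes named are drawn from those fixed by rule: the 10 with the largest change in each direction among genes past the threshold that moved the same way in every pair (5 for macrophage, T and endothelial nuclei), the 5 with the smallest p where fewer than 5 passed, up to 4 members per list by p, and the drug targets and their receptors. Genes of the interaction tests were chosen after their values were seen. Genes with 0 counts in a group are given as a bound at 3 counts over the group, and those with 1 to 3 as a ratio with its 95% counting interval. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and again with an estimated one. The lists covered TGF-beta response, myofibroblast, inflammatory and antigen-presenting fibroblasts, collagen and matrix, IL-1 and NF-kB, neutrophil chemokines, interferon, cytotoxic lymphocytes, T cell checkpoints, regulatory T cells, suppressive macrophages, EMT, classical and squamous epithelium, proliferation, hypoxia, axon guidance, complement and stress genes.

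Shares of nuclei were compared over matched pairs by an exact two-sided sign-flip permutation test, adjusted over 13 classes. The intron trend was a smooth fit of log2 fold change over genomic span divided by exon length. Alternatives covered the test, normalization, filter, calling of nuclei, doublets, empty-droplet RNA, depth, design, clusters and each library left out in turn. The fits were tested on simulated data. The labels give no numbers that pair animals, so a pair here is 2 libraries that share the other factors. Figures were drawn with matplotlib 3.10.9, and jsonlite 2.0.0 read the lists.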

Results

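Single-nucleus RNA was profiled in orthotopic pancreatic tumours grown in C57BL/6J mice from 2 KPC lines, KPC-4545 and KPC-3403. Each line received 6 treatments: control antibodies, a TGF-beta ligand trap (TGFB-TRAP), an antibody against interleukin-1 beta (anti-IL-1B), an antibody against the T cell checkpoint receptor PD-1 (anti-PD-1), and anti-PD-1 with either of the other agents. Each of the 12 groups was 1 library, so a treatment within a line had no replicate, and each factor was tested across the other factors. Whether a library is 1 mouse or a pool of mice is not stated in what was used here. In the order Control, TGFB-TRAP, anti-IL-1B, anti-PD-1, anti-PD-1 with TGFB-TRAP and anti-PD-1 with anti-IL-1B, the KPC-4545 libraries held 73052294, 36306721, 56665143, 34448714, 21683667 and 23177604 UMIs. The KPC-3403 libraries held 4214970, 7331356, 10140776, 12534661, 8037687 and 4477735 UMIs. In the same order, 4020, 2409, 4690, 2994, 1603 and 3212 nuclei were kept in KPC-4545 and 66, 513, 773, 1187, 98 and 8 in KPC-3403. The library of 8 nuclei entered the shares of cell classes and no test of genes. Ribosomal-RNA-like genes took 7.65 to 14.1% of UMIs in KPC-4545 without anti-PD-1, 17.5 to 23.1% with it and 20.6 to 69.9% in KPC-3403. Total UMIs were lower with anti-PD-1 in each KPC-4545 pair, so its effects there cannot be separated from such library differences.

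Clusters were named from fixed markers, and each name below means "like". Epithelial, macrophage/monocyte, fibroblast, mesothelial, erythroid, T, endothelial, dendritic, lymphatic endothelial, B, pericyte/smooth muscle, acinar and endocrine nuclei were found. Clusters left unnamed, by thresholds set after the data were seen, held 34.6, 47.6, 37.8, 39.9, 22.0 and 16.4% of the KPC-4545 libraries and 0, 13.3, 4.66, 2.53, 9.18 and 0% of the KPC-3403 libraries. Between 14.7 and 45.4% of the UMIs of a KPC-4545 library lay in nuclei, against 0.22 to 15.9% in KPC-3403, and the UMI minimum per nucleus ran from 500 to 1116, so shares can follow depth. Empty droplets among the nuclei of KPC-4545 Control and TGFB-TRAP are not excluded. With 1 library per group, a cluster mostly of 1 library may be that library. Intervals are exact 95% intervals and cover counting error only.

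**Figure D1:**
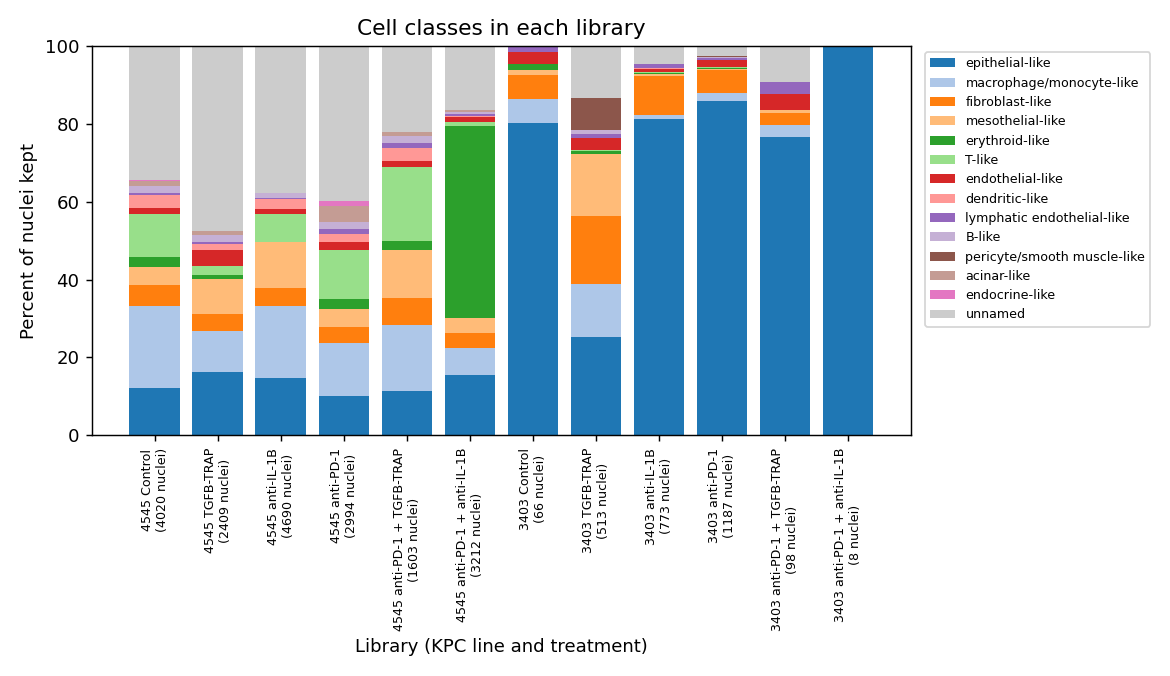
Percent of kept nuclei in each named class (bars stacked to 100%) for the 12 libraries, ordered by line and treatment, with the number of nuclei under each bar. Epithelial-like nuclei take 10.2 to 16.4% of each KPC-4545 library and 25.1 to 100% of each KPC-3403 library.

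The first comparison asks how the tumours of the lines differ. KPC-3403 libraries held more nuclei of the epithelial class: the share was 74.8% on average against 13.4% in KPC-4545, higher in 6 of 6 treatment-matched pairs (difference 61.4 ± 26.8 percentage points, SD, n = 6 pairs). It ran from 25.1% (21.4 to 29.1) with TGFB-TRAP to 85.9% (83.8 to 87.9) with anti-PD-1 in the 5 KPC-3403 libraries of over 8 nuclei. Counting the unnamed clusters 1, 3, 7, 11 and 21 as epithelial, an alternative chosen after the data were seen, gave 31.7 to 48.9% in KPC-4545 (38.7% on average) and the same values in KPC-3403. The share was then higher in 5 of 6 pairs, by 36.1 ± 27.7 points (adjusted p = 0.135 by the exact permutation test). Over the 3 pairs whose libraries each hold over 100 nuclei, T nuclei were 0.136% in KPC-3403 against 7.38% in KPC-4545, dendritic nuclei 0.043% against 2.09% and B nuclei 0.381% against 1.60%, each lower in 3 of 3. Over all 6 pairs, macrophage/monocyte nuclei were 4.33% against 14.6%, lower in 5, and fibroblast nuclei 7.12% against 4.86%, higher in 4. These values follow the calling of nuclei. The Monte Carlo test, which adds nuclei of lower UMIs, called 64 to 3656 barcodes in the KPC-4545 libraries, 267 in KPC-3403 anti-PD-1 and 0 in the other 5 KPC-3403 libraries. With OrdMag calls alone, T nuclei were 0.054% against 0.878% (lower in 5 of 6 pairs), macrophage/monocyte nuclei 4.19% against 4.30% (lower in 4 of 6), dendritic nuclei 0.022% against 0.422% and B nuclei 0.197% against 0.307%, while epithelial nuclei were 74.9% against 22.0%, higher in 6 of 6. By the exact two-sided sign-flip permutation test, 0 of 13 classes passed an adjusted p of 0.05. The epithelial difference had the smallest p that 6 pairs allow in this exact test, 0.0312, and adjusted p = 0.102. In the KPC-3403 libraries of 8, 66 and 98 nuclei, 3 nuclei would be 37.5, 4.55 and 3.06%, so the pairs with them decide nothing about rarer classes. An edgeR fit to counts of nuclei put 9 of the 13 classes past the threshold. Over all barcodes, Cd3e, a chain of the T cell receptor complex, stood at 25.9 and 27.5 CPM (UMIs scaled to the library sum) in KPC-3403 with anti-IL-1B and with anti-PD-1, within the KPC-4545 range of 12.3 to 32.0.

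In epithelial nuclei (11 libraries, 5 pairs), 7138 of 12003 genes differed between lines by edgeR at an adjusted p of 0.05, 3364 higher and 3774 lower in KPC-3403. Cldn18 (ENSMUSG00000032473, mm10 chromosome 9, 99689461 to 99717267), a tight-junction claudin of stomach-type epithelium, was at least 147-fold lower in KPC-3403, with 0 UMIs there against 2678. Nox4, an NADPH oxidase, was at least 109-fold lower, and Il1rapl1, a synaptic adhesion gene, at least 63.1-fold lower. These bounds set a floor of 3 counts over the group. On the log2 scale, Xist (ENSMUSG00000086503, chromosome X, 103460366 to 103483254), the RNA that silences an X chromosome in female cells, was higher by 5.25 ± 0.45 (SE, adjusted p = 4.39e-06). Grik5 (ENSMUSG00000003378, chromosome 7, 25009849 to 25072346), a kainate receptor subunit, was higher by 4.49 ± 0.27 (adjusted p = 1.33e-10). Tm4sf4, a tetraspanin-like gene, rose by 4.21 ± 0.88, Clec2f by 4.22 ± 0.61, Cdcp1 by 3.98 ± 0.84 and Tbx2, a T-box transcription factor, by 3.98 ± 0.74. Further rises were Ppp1r1b at 3.93 ± 0.48, Ugt1a7c at 3.86 ± 0.48, Tmem158 at 3.85 ± 0.41 and the chemokine receptor Cxcr2 at 3.67 ± 0.86, each in 5 of 5 pairs. Lrmda (at least 167-fold), Sh3gl2 (62.4), Dcc (45.3), Grm7 (39.4) and Cadps2 (21.5) had 0 UMIs in KPC-3403. Taco1 was lower by a log2 value of -9.85 ± 0.42, and Afm had 1 UMI in KPC-3403, a ratio of 0.00064 (1.62e-05 to 0.00357). Clusters 4, 9, 18 and 33 held these nuclei in KPC-4545 and clusters 2 and 19 in KPC-3403.

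The size of a gene's introns went with these differences. The median log2 difference between lines in epithelial nuclei fell from 1.30 over the 1586 genes whose genomic span was at most 2 times their exons to -3.75 over the 376 genes above 50 times. Over all barcodes, with mitochondrial genes, Malat1 and Gm42418 left out, all genes above 50 times, in any class, took 0.491 to 0.712% of UMIs in the 6 KPC-3403 libraries and 5.75 to 9.63% in KPC-4545. With this trend removed, an alternative chosen after the data were seen, 3763 epithelial genes passed. Of the genes named above, Sh3gl2 (adjusted p = 0.234), Grm7 (0.0538) and Dcc (0.109) no longer did, whereas Cldn18 (0.0153), Nox4 (0.0204), Xist (0.000105) and Grik5 (6.24e-11) did.

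**Figure D2:**
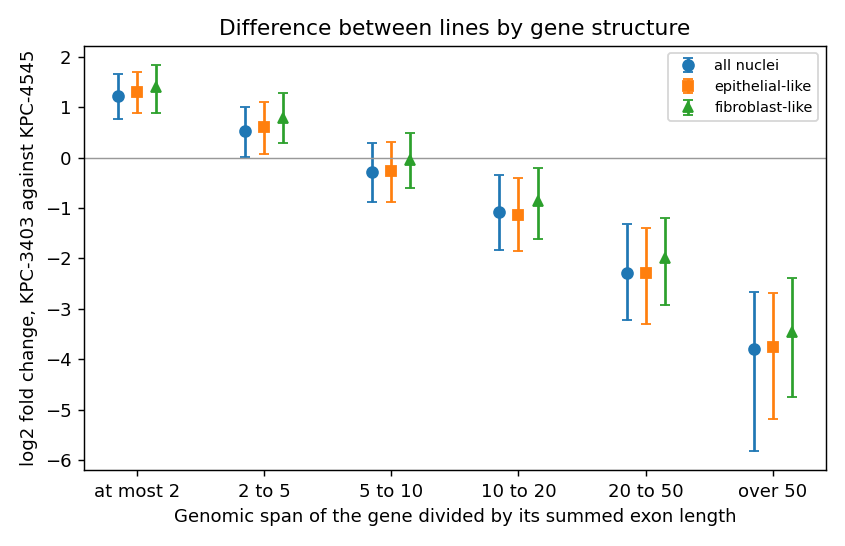
Log2 fold change, KPC-3403 against KPC-4545, by genomic span over summed exon length (6 bins), as medians with interquartile ranges over genes in all nuclei, epithelial-like and fibroblast-like nuclei. Medians fall from 1.30 to -3.75 in epithelial-like nuclei and from 1.41 to -3.46 in fibroblast-like nuclei.

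Of 17 measured proliferation genes in epithelial nuclei, 16 were higher in KPC-3403: 13 rose, 1 fell and 3 did not pass, and 15 rose and 1 fell adjusted over the list alone. With the intron trend removed, 8 rose and 0 fell. The list passed camera (adjusted p = 0.00144; adjusted p = 0.69 with an estimated correlation). Cenpf, a kinetochore protein, rose by 1.85 ± 0.19 and Top2a, a topoisomerase of dividing cells, by 1.71 ± 0.18, and with the intron trend removed they rose by 1.18 and 1.17. Diaph3, the member that fell (-1.95 ± 0.26), rose by 1.91 with the trend removed. Axon guidance and neural adhesion genes were lower: 1 of 20 was raised, 14 fell, 0 rose, and 15 fell adjusted over the list alone (adjusted p = 0.00144; adjusted p = 0.69 with an estimated correlation). Sema3e, a semaphorin, fell by 3.23 ± 0.22 and Slit2 by 2.35 ± 0.22, and both stayed lower with the trend removed, at -1.17 and -1.28. Slit3, a related guidance ligand, fell by 2.78 ± 0.33 but was higher by 1.22 with the trend removed, when 10 of the 20 members were raised. All 14 stress and immediate early genes were raised, 7 past the test over all genes and over the list alone (adjusted p = 0.0391; adjusted p = 0.975 with an estimated correlation). Junb, an AP-1 subunit, rose by 2.18 ± 0.18 and Jund by 1.99 ± 0.20, and 6 of the 14 members were raised with the trend removed.

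In fibroblast nuclei (9 libraries, 3 pairs), 2638 of 5982 genes differed, 1147 higher and 1491 lower, and 735 with the trend removed. Fabp4, a fatty acid binding protein, was higher by 3.62 ± 0.94, Fzd7, a Wnt receptor, by 3.44 ± 0.93, Pkhd1l1 by 3.42 ± 0.57, the small heat shock proteins Cryab and Hspb1 by 3.25 ± 0.89 and 2.94 ± 0.64, and Igfbp5 by 3.00 ± 0.56, each in 3 of 3 pairs. With the trend removed, Fabp4 (adjusted p = 0.128), Fzd7 (0.169), Cryab (0.0598) and Hspb1 (0.0865) no longer passed, and with cluster 6 added Pkhd1l1 turned to -0.69. Lrmda was at least 169-fold lower, Taco1 109-fold, Afm 51.1-fold and Prkd1, a protein kinase, 29.2-fold. Of 7 inflammatory fibroblast (iCAF) genes, 6 rose, over all genes and adjusted over the list alone (adjusted p = 0.0193; adjusted p = 0.42 with an estimated correlation). Among them were complement C3 at 1.79 ± 0.25, the hyaluronan synthase Has2 at 1.22 ± 0.25 and dermatopontin Dpt at 1.66 ± 0.42, and 5 of the 7 rose with the trend removed. Of 20 collagen and matrix genes, 10 rose and 2 fell (11 and 3 adjusted over the list alone; adjusted p = 0.0193; adjusted p = 0.503 with an estimated correlation), with decorin (Dcn) at 2.01 ± 0.23. Antigen-presenting fibroblast (apCAF) genes had 4 of 6 past both tests (adjusted p = 0.0242; adjusted p = 0.42 with an estimated correlation), with Slpi at 3.03 ± 0.69. Interferon response genes had 9 of 19 past both, all higher (adjusted p = 0.0193; adjusted p = 0.452 with an estimated correlation), with Cxcl10 at 2.64 ± 0.34. Complement genes had 6 of 11 higher (adjusted p = 0.0193; adjusted p = 0.452 with an estimated correlation), stress genes 4 of 6 higher and axon guidance genes 8 of 17 lower and 1 higher (each adjusted p = 0.0193; adjusted p = 0.42 with an estimated correlation). These counts were the same adjusted over the list alone. With the trend removed, 6 collagen and matrix genes, 2 apCAF, 2 interferon, 4 complement, 1 stress and 1 axon guidance gene were higher, and 0, 0, 1, 1, 1 and 3 were lower. Cluster 8 held these nuclei in KPC-4545 and 3 parts of cluster 15 in KPC-3403.

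Summed over all nuclei, which mixes cell classes, 8233 of 14623 genes differed (3753 higher, 4480 lower), and 4224 with the trend removed. Dlx2, a homeobox gene, was higher by 5.38 ± 1.02, Clec2f by 5.12 ± 0.68, Tm4sf4 by 4.94 ± 0.82 and Ppp1r1b by 4.79 ± 0.51 in 5 of 5 pairs. Lrmda was at least 1260-fold lower, Cldn18 at least 81.8-fold, Tafa2 at least 52.9-fold and Tafa1 at least 46.7-fold. Axon guidance genes fell in 15 of 21 (17 adjusted over the list alone; adjusted p = 0.00213; adjusted p = 0.69 with an estimated correlation). Stress genes rose in 9 of 14 (10 adjusted over the list alone; adjusted p = 0.00195; adjusted p = 0.69 with an estimated correlation). Proliferation genes rose in 6 of 17 and fell in 1, over all genes and adjusted over the list alone (adjusted p = 0.0417; adjusted p = 0.834 with an estimated correlation). With the trend removed, 5 axon guidance genes fell and 3 rose, 3 stress genes rose and 1 fell, and 6 proliferation genes rose.

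The next comparison asks what depleting TGF-beta ligands did, with TGFB-TRAP set against no second agent. In fibroblast nuclei the matrix gene tenascin C (Tnc, ENSMUSG00000028364, chromosome 4, 63959785 to 64047015), a TGF-beta target, fell by 2.19 ± 0.33 on the log2 scale (SE, 9 libraries, adjusted p = 0.00293, lower in 2 of 2 pairs). The neuron navigator Nav3 fell by 1.70 ± 0.30 (adjusted p = 0.00471). Abca9, a lipid transporter, rose by 2.49 ± 0.45 (adjusted p = 0.00532) and C3 by 1.20 ± 0.28 (adjusted p = 0.0312), both in 2 of 2 pairs. In all, 79 of 5982 genes changed by edgeR, 55 higher and 24 lower, against 8 by DESeq2. Macrophage and lymphocyte genes were among those that rose: the mannose receptor Mrc1 at 1.97 ± 0.38, Tbxas1 at 2.10 ± 0.39 and Myo1f at 1.95 ± 0.36. The immunoglobulin gene Igkc rose by 3.62 ± 0.63, Ighm by 2.26 ± 0.47, Blnk by 2.93 ± 0.66 and Ripor2 by 2.03 ± 0.42. The macrophage product Retnla had 37 UMIs against 1, a ratio of 73.6 (12.4 to 2980). The empty droplets of the same KPC-4545 libraries differed by 3.37 for Igkc, 2.50 for Ighm and 3.31 for Retnla. Macrophage markers measured in these nuclei were raised in 11 of 12, with a median of 0.63. Dpt rose by 1.80 ± 0.43 and the class II regulator Ciita by 1.70 ± 0.35, while Has2 fell by 1.10 ± 0.28, and by 1.10 between the empty droplets of the same libraries. The calcium-binding S100a11 fell by 2.07 ± 0.39, S100a10 by 1.77 ± 0.40 and the glycolytic Gapdh by 2.63 ± 0.54. Dpp6 fell by 2.52 ± 0.55, Adgrl3 by 1.54 ± 0.36, Rpl14 by 1.54 ± 0.40 and Gxylt2 by 1.47 ± 0.38. Zfp804a had 1 UMI with the trap, a ratio of 0.0276 (0.00069 to 0.159). In KPC-3403, where no fibroblast pair could be formed, Mrc1 stood at 40.8 CPM with TGFB-TRAP against 91.2 with anti-PD-1 alone.

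None of 12 myofibroblast (myCAF) genes was raised in these fibroblasts, and 1 fell, Tnc, over all genes and adjusted over the list alone (adjusted p = 0.000238; adjusted p = 0.339 with an estimated correlation). Hypoxia and glycolysis genes were raised in 2 of 12, with 0 past the test over all genes and 3 lower adjusted over the list alone (adjusted p = 0.00127; adjusted p = 0.339 with an estimated correlation). Classical-type epithelial genes were raised in 0 of 7, with 1 lower adjusted over the list alone (adjusted p = 0.00302; adjusted p = 0.339 with an estimated correlation). Of 11 complement genes 10 were raised; 1 rose, and 3 adjusted over the list alone (adjusted p = 0.0469; adjusted p = 0.433 with an estimated correlation). The TGF-beta response list, raised in 3 of 16, did not pass (adjusted p = 0.065; adjusted p = 0.339 with an estimated correlation). The count of 79 became 2 without the KPC-4545 Control library, 15 without KPC-4545 TGFB-TRAP, 42 without KPC-4545 anti-PD-1 with TGFB-TRAP, 49 without KPC-3403 anti-PD-1, and 10 with the unnamed cluster 10 added. Tnc passed in all 22 alternatives run, and C3 turned to -0.24 with cluster 6 added.

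In epithelial nuclei 0 of 12003 genes passed with TGFB-TRAP by edgeR (611 at an unadjusted p under 0.05; DESeq2 0). The genes with the smallest p were Igkc at 3.07, apolipoprotein Apoa1 at 4.74, Cited2 at -1.74, Sprr1a at -1.62 and Mab21l4 at -2.49. As a list, the TGF-beta response genes were lower: 4 of 18 were raised, with 5 lower adjusted over the list alone (adjusted p = 0.0137; adjusted p = 0.956 with an estimated correlation). Examples are Pmepa1, a feedback inhibitor of the pathway, at -0.86 ± 0.25 in 3 of 4 pairs (4 without TMM factors), the Smad corepressor Skil at -0.92 ± 0.27 in 4 of 4, and Ccn2 at -1.24 ± 0.35 in 3 of 4. Hypoxia genes were raised in 1 of 16, with 3 lower adjusted over the list alone (adjusted p = 0.0168; adjusted p = 0.956 with an estimated correlation), as Bnip3 at -0.88 ± 0.29. Proliferation genes were raised in 13 of 17, with 0 past the test either way (adjusted p = 0.0137; adjusted p = 0.956 with an estimated correlation). Over all nuclei 0 genes passed by edgeR (1166 at an unadjusted p under 0.05; DESeq2 66), with Kcnd2 at 3.00 ± 0.48, Klhl29 at 2.29 ± 0.37, Wipf3 at 3.29 ± 0.56, elastin (Eln) at 1.62 ± 0.29 and Kcnab1 at 2.42 ± 0.41 at the smallest p. There, 17 of 20 collagen and matrix genes were raised, 1 past the test adjusted over the list alone (adjusted p = 0.00254; adjusted p = 0.946 with an estimated correlation), with Col6a1 at 0.89 ± 0.23 in 4 of 4 pairs. Fibroblast and pericyte/smooth muscle nuclei were 17.3 and 8.38% of KPC-3403 TGFB-TRAP, where Col6a1 stood at 329 CPM against 89.3 in KPC-3403 Control, and at 81.5 against 74.1 in KPC-4545. Of 12 complement genes 10 were raised, 6 past it adjusted over the list alone (adjusted p = 0.0138; adjusted p = 0.946 with an estimated correlation). Leaving out KPC-4545 TGFB-TRAP, KPC-4545 anti-PD-1 with TGFB-TRAP and KPC-3403 TGFB-TRAP gave 128, 48 and 17 genes over all nuclei. In epithelial nuclei the counts were 12 without KPC-4545 Control, 12 without KPC-4545 anti-PD-1 with TGFB-TRAP and 1 without KPC-4545 TGFB-TRAP. Mesothelial nuclei were 9.61% with TGFB-TRAP against 2.74%, higher in 4 of 4 pairs (adjusted p = 0.812, at the smallest p that 4 pairs allow in the exact sign-flip permutation test), and 0 of 13 classes passed by that test or by edgeR.

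Macrophage, T and endothelial nuclei were too few in KPC-3403 for the planned fits, so KPC-4545 alone was fitted, a choice made after the data were seen (6 libraries). In macrophages with TGFB-TRAP, 2 genes rose, Retnla by 5.87 ± 0.69 and Igkc by 3.57 ± 0.39 (both adjusted p = 0.0122, 2 of 2 pairs). This count became 0 without Control or anti-PD-1, 30 without TGFB-TRAP, 17 without anti-IL-1B, 324 without anti-PD-1 with TGFB-TRAP and 23 without anti-PD-1 with anti-IL-1B. In T and endothelial nuclei 0 genes passed by edgeR (283 and 282 at an unadjusted p under 0.05; DESeq2 0 in both). Left out in turn, TGFB-TRAP, anti-PD-1, anti-PD-1 with TGFB-TRAP and anti-PD-1 with anti-IL-1B gave 5, 2, 7 and 12 genes in T nuclei and 10, 34, 109 and 40 in endothelial nuclei, where anti-IL-1B gave 21. In endothelial nuclei iCAF genes were raised in 4 of 4 (adjusted p = 0.0146), classical-type epithelial genes in 0 of 4 (adjusted p = 0.0021) and proliferation genes in 0 of 6 (adjusted p = 0.0382), each at adjusted p = 0.564 with an estimated correlation, with 1, 1 and 0 past the test adjusted over the list alone and 0 over all genes. In T nuclei classical-type epithelial genes were raised in 1 of 7, with 0 past it either way (adjusted p = 0.0359; adjusted p = 0.948 with an estimated correlation).

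The comparison for anti-IL-1B asks what blocking this inflammatory cytokine did. No gene passed in fibroblast, epithelial or all nuclei by edgeR (364, 355 and 285 at an unadjusted p under 0.05; DESeq2 0 in each). Over the 2 pairs whose libraries each hold over 100 nuclei, both of KPC-4545, 9 of the 13 classes were lower in 2 of 2. The largest differences were in T nuclei, at 4.07% with anti-IL-1B against 11.9%, and macrophage/monocyte nuclei, at 12.7% against 17.3%. Dendritic nuclei were 1.57% against 2.77%, B nuclei 0.884% against 1.69%, endothelial 1.26% against 1.79% and lymphatic endothelial 0.297% against 0.963%. Acinar, endocrine and fibroblast nuclei were the others, and epithelial nuclei were 15.2% against 11.2%, higher in 2 of 2. Of KPC-4545 anti-PD-1 with anti-IL-1B, 49.3% were erythroid nuclei. This lowers each other share there, so falls in that pair, and thus the count of 9, can follow from it. Without clusters 0, 27, 28 and 31, an alternative chosen after the data were seen, endothelial nuclei were lower in 3 of 4 pairs and macrophage/monocyte nuclei were 8.28% against 10.9%, and with OrdMag calls alone the latter were 2.59% against 2.77%, lower in 2 of 4. Epithelial nuclei with clusters 1, 3, 7, 11 and 21 added were 63.4% against 63.3%, higher in 3 of 4. By the exact permutation test 0 of 13 classes passed (smallest adjusted p = 0.406). The genes with the smallest p over all nuclei were Gpr149 at -5.08 ± 0.88, the Wnt inhibitor Dkk2 at -1.87, Sp110 at 0.91, Eya4 at 1.46 and Hsph1 at -1.11. In epithelial nuclei they were Asz1 at -3.21, the muscarinic receptor Chrm3 at -2.06, Dcdc2a at -2.08, Cadps2 at -2.82 and the nuclear receptor Nr5a2 at -3.44. In fibroblasts they were Kcnma1 at -1.62, Spsb1 at -1.36, Tmem108 at -1.88, Tafa2 at 3.18 and A2m, with 1 UMI against 78, a ratio of 0.0251 (0.000628 to 0.144). Left out in turn, KPC-4545 TGFB-TRAP, KPC-4545 anti-IL-1B, KPC-4545 anti-PD-1 with TGFB-TRAP, KPC-4545 anti-PD-1 with anti-IL-1B, KPC-3403 TGFB-TRAP and KPC-3403 anti-PD-1 gave 2, 3, 2, 9, 1 and 1 genes over all nuclei. In fibroblasts KPC-4545 anti-IL-1B, KPC-4545 anti-PD-1, KPC-3403 TGFB-TRAP, KPC-3403 anti-IL-1B and KPC-3403 anti-PD-1 gave 7, 1, 1, 2 and 1, and in epithelial nuclei KPC-4545 Control gave 2. The list of IL-1 and NF-kB response genes did not pass, with 5 of 19 raised in epithelial nuclei (adjusted p = 0.287) and 11 of 19 in all nuclei (adjusted p = 0.831).

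Collagen and matrix genes with anti-IL-1B were raised in 2 of 20 in fibroblasts (adjusted p = 0.00166; adjusted p = 0.691 with an estimated correlation) and in 14 of 19 in epithelial nuclei (adjusted p = 0.0142; adjusted p = 0.709 with an estimated correlation). In epithelial nuclei apCAF genes were raised in 5 of 6 (adjusted p = 0.0227) and cytotoxic lymphocyte genes in 4 of 4 (adjusted p = 0.0241), both at adjusted p = 0.709 with an estimated correlation. Over all nuclei interferon response genes were raised in 22 of 24 (adjusted p = 0.00946) and apCAF genes in 6 of 7 (adjusted p = 0.0452), both at adjusted p = 0.961 with an estimated correlation. In each of these lists 0 members passed over all genes, and 0 adjusted over the list alone. In the KPC-4545 T nuclei 3 genes passed (DESeq2 0): Dgkg at 3.45 ± 0.81, Dmbt1, with 2 UMIs against 195, a ratio of 0.0302 (0.00363 to 0.111), and the acinar protease Ctrb1 at -3.86 ± 0.70 in 1 of 2 pairs. They became 0 without anti-IL-1B or anti-PD-1, 5 without anti-PD-1 with TGFB-TRAP and 8 without anti-PD-1 with anti-IL-1B. In KPC-4545 macrophage and endothelial nuclei 0 genes passed by edgeR (149 and 223 at an unadjusted p under 0.05; DESeq2 0 in both). Left out in turn, TGFB-TRAP, anti-IL-1B, anti-PD-1 with TGFB-TRAP and anti-PD-1 with anti-IL-1B gave 28, 22, 33 and 11 genes in macrophages and 33, 27, 46 and 19 in endothelial nuclei, where Control gave 1 and anti-PD-1 gave 22.

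The last main comparison asks what PD-1 blockade did. Some matrix genes fell in fibroblast nuclei with anti-PD-1: Tnc fell by 1.52 ± 0.28 on the log2 scale (SE, 9 libraries, adjusted p = 0.00679), the myofibroblast marker Lrrc15 (ENSMUSG00000052316, chromosome 16, 30269302 to 30283256) by 1.93 ± 0.50 (adjusted p = 0.0447) and the collagen VI chain Col6a3 by 1.14 ± 0.25 (adjusted p = 0.0199), each in 3 of 3 pairs. Of 12 myCAF genes 1 was raised, 2 fell and 10 did not pass, and 4 fell adjusted over the list alone (adjusted p = 0.000254; adjusted p = 0.363 with an estimated correlation). Of 20 collagen and matrix genes 5 were raised and 1 fell, and 6 fell adjusted over the list alone (adjusted p = 0.00484; adjusted p = 0.363 with an estimated correlation). Proliferation genes were raised in 0 of 8, with 1 lower adjusted over the list alone (adjusted p = 0.015; adjusted p = 0.363 with an estimated correlation). In all 101 of 5982 genes changed by edgeR, 40 higher and 61 lower, against 11 by DESeq2. The T cell signalling genes Themis at 2.35 ± 0.37, Cd247 at 2.08 ± 0.49 and Grap2 at 1.97 ± 0.35 rose, and so did Chrm3 at 2.37 ± 0.56 (-0.34 with cluster 6 added) and Taco1 at 1.86 ± 0.32. Themis, Cd247 and Grap2 are among the 10 leading genes of the T cluster 5, and the first 2 lie below their level in empty droplets. Leaving out such genes gave 23 genes in all, OrdMag calls alone 12 and thinning 19. Ppargc1b rose by 1.80 ± 0.46, Ctnna3 by 1.70 ± 0.36, the kinase Cdk8 by 1.69 ± 0.27 and the growth factor Fgf7 by 1.63 ± 0.34. Galectin-1 (Lgals1) fell by 2.36 ± 0.42, Trpc6 by 2.29 ± 0.47 and ubiquitin B (Ubb) by 2.08 ± 0.52. The respiratory chain genes Atp5j fell by 2.01 ± 0.50 and Cox8a by 1.95 ± 0.39, and the ribosomal protein genes Rpl10 by 1.95 ± 0.43, Rpl22l1 by 1.84 ± 0.41 and Rpl36 by 1.77 ± 0.37. Zfp804a had 3 UMIs against 117, a ratio of 0.0743 (0.0151 to 0.223). The count became 4 without KPC-4545 Control, 5 without KPC-4545 anti-PD-1 and 51 without KPC-4545 anti-PD-1 with anti-IL-1B, and 47 with the intron trend removed. Over all barcodes, genes of span over 50 times their exons took 9.22 to 9.63% of UMIs in KPC-4545 with anti-PD-1 and 5.75 to 6.30% without, in 3 of 3 pairs. The unnamed cluster 10, which matches fibroblasts in its markers, held 288, 190 and 311 nuclei without anti-PD-1 and 29, 14 and 11 with it in KPC-4545. Adding it took Tnc to -0.41 (adjusted p = 0.658) and Col6a3 to -0.31 (adjusted p = 0.715).

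In epithelial nuclei 9 of 12003 genes changed with anti-PD-1 (7 higher, 2 lower; DESeq2 9). Chrm3 (ENSMUSG00000046159, chromosome 13, 9875486 to 10360847), the M3 muscarinic acetylcholine receptor, rose by 3.41 ± 0.30 (SE, 11 libraries, adjusted p = 5.65e-06), Onecut1, a pancreatic duct and liver transcription factor, by 2.73 ± 0.39 (adjusted p = 0.0035) and Dcdc2a, a ciliary gene, by 2.55 ± 0.31 (adjusted p = 0.000512), each in 5 of 5 pairs. Matrix Gla protein (Mgp) fell by 1.80 ± 0.32 (adjusted p = 0.0261, 5 of 5 pairs, or 4 by CPM without TMM factors), apolipoprotein E (Apoe) by 1.77 ± 0.28 in 4 of 5 pairs, and Nkx2-2os rose by 3.40 ± 0.52 in 4 of 5. In the KPC-4545 libraries alone the count was 0, with Chrm3 at 3.48, Onecut1 at 2.86 and Dcdc2a at 2.61 (each adjusted p = 0.0565), and thinning or a filter at 20 counts also gave 0. Leaving out KPC-4545 Control, KPC-4545 TGFB-TRAP, KPC-4545 anti-PD-1, KPC-4545 anti-PD-1 with TGFB-TRAP, KPC-3403 anti-IL-1B, KPC-3403 anti-PD-1 and KPC-3403 anti-PD-1 with TGFB-TRAP gave 124, 22, 15, 21, 29, 24 and 5 genes. The small cluster 33 of this class, with Dcdc2a, Chrm3 and Onecut1 among its 10 leading genes, held 31, 21 and 5 nuclei in the KPC-4545 libraries with anti-PD-1 and 2, 17 and 0 without, and 0 in KPC-3403.

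Interferon response genes in epithelial nuclei were raised in 22 of 24 with anti-PD-1, 0 past the test over all genes and 5 adjusted over the list alone (adjusted p = 1.65e-06; adjusted p = 0.36 with an estimated correlation). The PD-1 ligand Cd274 was at 1.00 ± 0.26 in 5 of 5 pairs with TMM factors and 4 of 5 by CPM without them, the class I regulator Nlrc5 at 0.76 in 5 of 5, and Ido1, which degrades tryptophan, at 1.54 in 3 of 5. IL-1 and NF-kB response genes were raised in 16 of 19, 3 adjusted over the list alone (adjusted p = 0.00445), cytotoxic genes in 4 of 4 (adjusted p = 0.000329) and neutrophil-recruiting chemokine genes in 5 of 7 (adjusted p = 0.0345), the latter lists with 0 past the test either way and all at adjusted p = 0.36 with an estimated correlation. Collagen and matrix genes were raised in 0 of 19, 8 lower adjusted over the list alone (adjusted p = 2e-05), myCAF genes in 1 of 11, 2 lower (adjusted p = 0.00771), and T cell checkpoint genes in 6 of 6, 0 past it (adjusted p = 0.0282), all at adjusted p = 0.423 with an estimated correlation. In most of the 11 libraries, 4 of the 4 cytotoxic, 6 of the 6 checkpoint, 19 of the 19 collagen, 10 of the 11 myCAF and 20 of the 24 interferon genes lay below their level in empty droplets, a comparison chosen after the data were seen. Between the empty droplets of the same 5 pairs the median log2 difference was 0.96 for cytotoxic genes (1.32 in epithelial nuclei), 0.42 for checkpoint genes (0.50), -0.80 for collagen genes (-0.83), -0.59 for myCAF genes (-0.91) and 0.27 for interferon genes (0.58). It was -0.07 for IL-1 and NF-kB genes (0.25) and -0.03 for the chemokine genes (0.25).

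Over all nuclei 0 genes passed with anti-PD-1 by edgeR (1123 at an unadjusted p under 0.05; DESeq2 19), with Apol10b at 1.88 ± 0.30, Dcdc2a at 2.60 ± 0.42, Myo3a at -1.83 ± 0.30, Fstl4 at 2.02 and Nkx2-2os at 3.21 at the smallest p. Left out in turn, KPC-4545 Control, KPC-4545 TGFB-TRAP, KPC-4545 anti-PD-1 with TGFB-TRAP, KPC-3403 TGFB-TRAP and KPC-3403 anti-IL-1B gave 1, 66, 65, 21 and 7. All 11 cytotoxic lymphocyte genes were raised, 5 past the test adjusted over the list alone (adjusted p = 1.12e-05), with granzymes Gzma at 1.57 ± 0.39 and Gzmb at 1.58 ± 0.48 and the CD8 chain Cd8b1 at 1.21, each in 5 of 5 pairs. All 10 checkpoint and exhaustion genes were raised, 0 past it (adjusted p = 0.0046), with Pdcd1, which encodes PD-1, at 1.02 and Lag3 at 0.85 in 5 of 5 pairs. Interferon genes were raised in 21 of 24 (1 past it, adjusted p = 8.85e-05) and IL-1 and NF-kB genes in 12 of 19 (0 past it, adjusted p = 0.00638). MyCAF genes were raised in 1 of 14 (10 lower adjusted over the list alone, adjusted p = 5.8e-06) and suppressive macrophage genes in 2 of 12 (2 lower, adjusted p = 0.00015). These 6 lists had adjusted p = 0.331 with an estimated correlation. Collagen and matrix genes were raised in 0 of 20 (6 lower adjusted over the list alone, adjusted p = 1.17e-05) and proliferation genes in 17 of 17 (0 past it, adjusted p = 0.00236), both at adjusted p = 0.423 with an estimated correlation. Complement genes were raised in 1 of 12 (2 lower adjusted over the list alone, adjusted p = 0.0491; adjusted p = 0.696 with an estimated correlation). Over all genes 0 members of these lists passed. Macrophage/monocyte nuclei were 6.995% with anti-PD-1 against 11.9%, lower in 5 of 6 pairs (exact permutation p = 0.156, adjusted p = 0.677), T nuclei 5.47% against 3.48%, higher in 3 of 6 (p = 0.719, adjusted p = 0.779), and 0 of 13 classes passed (edgeR 1, endocrine nuclei, 38 of whose 43 nuclei lay in KPC-4545 anti-PD-1).

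Among the KPC-4545 T nuclei (6 libraries, 3 pairs), 259 of 7089 genes changed with anti-PD-1, 14 higher and 245 lower (DESeq2 59). Havcr2, which encodes the exhaustion receptor TIM-3, rose by 1.16 ± 0.34 (adjusted p = 0.019, 3 of 3 pairs), and the sulfotransferase Sult2b1 by 2.97 ± 0.75. Taco1 rose by 1.60 ± 0.36 and March3 by 1.29 ± 0.38. Of 10 checkpoint genes 9 were raised and Havcr2 was the 1 that rose, over all genes and adjusted over the list alone (adjusted p = 0.0108; adjusted p = 0.734 with an estimated correlation). Of 12 cytotoxic genes 10 were raised, 0 past the test either way (adjusted p = 0.00985; adjusted p = 0.64 with an estimated correlation). Genes of other cell types were lower: cystatin C (Cst3) fell by 3.06 ± 0.49, Apoe by 2.36 ± 0.38, osteonectin (Sparc) by 1.55 ± 0.34, the class II chain Cd74 by 1.90 ± 0.35 and keratin 8 (Krt8) by 1.30 ± 0.34, with Cox8a at -2.77 ± 0.42 and Trmt112 at -2.74 ± 0.60. Tmem258 and Htra1 had 3 UMIs each with anti-PD-1, ratios of 0.0562 (0.0114 to 0.168) and 0.0833 (0.0169 to 0.252). All 16 collagen and matrix genes were lower, 7 fell and 12 fell adjusted over the list alone (adjusted p = 1.28e-07). In the same order, myCAF genes (0 of 9 raised) had 5 and 6 lower (adjusted p = 0.000189) and classical-type epithelial genes (0 of 7) had 4 and 5 lower (adjusted p = 0.000727). These 3 lists had adjusted p = 0.379 with an estimated correlation. The apCAF genes were raised in 0 of 6, with 4 and 5 lower (adjusted p = 0.00022; adjusted p = 0.462 with an estimated correlation). Suppressive macrophage genes (0 of 7 raised; 2 and 4 lower; adjusted p = 0.00782), complement genes (0 of 7; 1 and 3 lower; adjusted p = 0.0462) and stress genes (0 of 7; 1 and 3 lower; adjusted p = 0.0057) had adjusted p = 0.506 with an estimated correlation. Hypoxia genes were raised in 2 of 13, with 3 lower, and 4 lower and 1 higher adjusted over the list alone (adjusted p = 0.0334; adjusted p = 0.64 with an estimated correlation). Without genes below their level in empty droplets the count was 15, and 20 with no filter on low counts. It became 0 without anti-PD-1, 1 without Control, 70 without TGFB-TRAP, 126 without anti-IL-1B, 65 without anti-PD-1 with TGFB-TRAP, and 105 with the intron trend removed.

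In KPC-4545 macrophages 60 of 8014 genes changed with anti-PD-1, 3 higher and 57 lower (DESeq2 73). The adhesion gene Cadm1 rose by 0.98 ± 0.19, while Mgp fell by 2.74 ± 0.37, the matrix gene periostin (Postn) by 2.53 ± 0.48, Nop10 by 3.08 ± 0.60, Atp5mpl by 2.47 ± 0.38 and Tmem258 by 2.47 ± 0.47, each in 3 of 3 pairs. Of 19 collagen and matrix genes 0 were raised, 2 fell and 9 fell adjusted over the list alone (adjusted p = 6.77e-08), and of 10 myCAF genes 0 were raised, with 2 and 9 lower (adjusted p = 4.17e-07). Classical-type epithelial genes were raised in 1 of 8 (1 and 6 lower, adjusted p = 0.00089), suppressive macrophage genes in 2 of 11 (0 and 2 lower, adjusted p = 0.00606) and IL-1 and NF-kB genes in 12 of 15 (0 either way, adjusted p = 0.00517). These 5 lists had adjusted p = 0.536 with an estimated correlation, and complement genes, raised in 1 of 12 with 0 past the test either way, had adjusted p = 0.00309 and adjusted p = 0.618 with an estimated correlation. The count became 0 with the intron trend removed, without genes below their level in empty droplets, or at 20 counts, 1 with OrdMag calls alone, 105 thinned, 117 at 1000 UMIs and 318 with no filter. It became 0 without anti-PD-1, 1 without Control, 559 without TGFB-TRAP, 123 without anti-IL-1B, 513 without anti-PD-1 with TGFB-TRAP and 224 without anti-PD-1 with anti-IL-1B. In KPC-4545 endothelial nuclei 2 genes changed, the potassium channel Kcnma1 at 2.62 ± 0.35 (adjusted p = 0.0448) and Ighm at -3.96 ± 0.42 (adjusted p = 0.0109) in 3 of 3 pairs (DESeq2 4), a count that became 41 without Control, 103 without TGFB-TRAP, 129 without anti-IL-1B, 42 without anti-PD-1, 101 without anti-PD-1 with TGFB-TRAP and 175 without anti-PD-1 with anti-IL-1B. There, collagen and matrix (0 of 15 raised, adjusted p = 1.62e-07), complement (0 of 7, adjusted p = 0.00045), classical-type epithelial (0 of 4, adjusted p = 0.00056), suppressive macrophage (1 of 4, adjusted p = 0.00791) and apCAF genes (0 of 5, adjusted p = 0.0132) had 0 members past the test over all genes. Adjusted over the list alone, 9, 3, 4, 3 and 3 of them were lower, and all 5 lists had adjusted p = 0.366 with an estimated correlation. MyCAF genes were raised in 1 of 8, 2 lower adjusted over the list alone (adjusted p = 0.0345; adjusted p = 0.372 with an estimated correlation). Fibroblast, epithelial and acinar markers, relative to empty droplets, were lower with anti-PD-1 in endothelial nuclei in 3 of 3 pairs (44.2 against 61.6%, 29.6 against 75.6% and 46.3 against 62.4%). In macrophages they were lower in 2 of 3 (36.0 against 55.0%, 32.4 against 55.2% and 48.8 against 38.6%). In the first 2 pairs the library without anti-PD-1 had an empty median of 5 UMIs, against 232 and 148 in its match. The empty droplets are thus not alike between these libraries, and the counts of pairs decide nothing about free RNA.

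Whether an effect differed between groups was tested by interaction terms. Between the lines, 0 genes differed over all nuclei in the TGFB-TRAP, anti-IL-1B and anti-PD-1 effects by edgeR (503, 439 and 905 at an unadjusted p under 0.05; DESeq2 1, 0 and 7). Left out in turn, KPC-4545 TGFB-TRAP, KPC-4545 anti-IL-1B, KPC-4545 anti-PD-1 with TGFB-TRAP and KPC-4545 anti-PD-1 with anti-IL-1B gave 7, 1, 7 and 6 genes for anti-IL-1B and 9, 1, 7 and 3 for anti-PD-1. In epithelial nuclei 0, 0 and 1 differed (263, 273 and 546 at an unadjusted p under 0.05; DESeq2 0, 1 and 4). For TGFB-TRAP the count was 2, 1, 3 and 1 without KPC-4545 Control, KPC-4545 TGFB-TRAP, KPC-4545 anti-PD-1 and KPC-4545 anti-PD-1 with anti-IL-1B, and for anti-IL-1B it was 1, 16 and 2 without the last 3 of these. The gene was the collagen I chain Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042), whose anti-PD-1 effect was higher in KPC-3403 by 2.87 ± 0.45 (adjusted p = 0.0342). It gave way to 0 genes when thinned, at 20 counts, with median-of-ratios size factors or without genes below their level in empty droplets. For this effect 0 genes passed without KPC-4545 anti-PD-1 with TGFB-TRAP, KPC-3403 Control, KPC-3403 anti-PD-1 or KPC-3403 anti-PD-1 with TGFB-TRAP, 2 without KPC-4545 Control, 5 without KPC-4545 anti-PD-1 and 6 without KPC-3403 TGFB-TRAP. The TGFB-TRAP effect differed with anti-PD-1 for 50 genes in epithelial nuclei (23 higher and 27 lower with both agents; DESeq2 1), among them Bcas1 at 5.42 ± 0.90, the anchoring collagen Col7a1 at -3.27 ± 0.55 and Has2 at -2.90 ± 0.53. Over all nuclei 18 genes differed (DESeq2 2), among them insulin (Ins2), glucagon (Gcg), albumin (Alb) and Has2, the last at -2.54 ± 0.45, and in fibroblasts 3 (DESeq2 0), of which Nlgn1 is named and the others are predicted genes. Endocrine nuclei were 1.27% of KPC-4545 anti-PD-1 and at most 0.0934% of each other library, and Alb stood at 294 CPM over all barcodes of KPC-4545 TGFB-TRAP. The fibroblast count became 0 without KPC-4545 TGFB-TRAP or KPC-4545 anti-PD-1, and 1 without KPC-4545 anti-IL-1B, KPC-3403 anti-IL-1B or KPC-3403 anti-PD-1. The counts of 50 and 18 became 3 and 0 when thinned, 10 and 0 at 20 counts and 147 and 71 with no filter. Without KPC-4545 Control or KPC-4545 anti-PD-1 with TGFB-TRAP both became 0. Over all nuclei, leaving out KPC-4545 TGFB-TRAP, KPC-4545 anti-IL-1B, KPC-4545 anti-PD-1, KPC-3403 TGFB-TRAP, KPC-3403 anti-IL-1B, KPC-3403 anti-PD-1 and KPC-3403 anti-PD-1 with TGFB-TRAP gave 239, 55, 28, 217, 61, 141 and 1. Leaving out KPC-4545 anti-IL-1B, KPC-3403 Control, KPC-3403 TGFB-TRAP, KPC-3403 anti-PD-1 and KPC-3403 anti-PD-1 with TGFB-TRAP gave 24, 149, 107, 111 and 22 epithelial genes.

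The drug targets were detected in each library, over all barcodes. Tgfb1 stood at 53.4 to 119.6 CPM, Tgfb2 at 4.11 to 27.04, Tgfb3 at 7.71 to 43.3 and Il1b at 8.71 to 76.8, the last highest in KPC-3403 with TGFB-TRAP (76.8, 70.6 to 83.4) and with anti-PD-1 (76.8, 72.05 to 81.8). Pdcd1 stood at 6.09, 3.91 and 8.70 in KPC-4545 without anti-PD-1 (Control, TGFB-TRAP, anti-IL-1B) and at 8.71, 11.99 and 14.1 with it, and at 0.89 to 3.59 in KPC-3403. Cd274 ran from 25.4 to 98.8, Tgfbr1 from 13.6 to 210.0, Tgfbr2 from 11.6 to 180.5 and Il1r1 from 10.8 to 231. In KPC-4545 the interleukin-1 receptor Il1r1 was at 226 with TGFB-TRAP against 155 in Control, and at 231 against 123 with anti-PD-1. In KPC-3403 it was at 43.1 against 20.9, and lower at 10.8 against 36.9 with anti-PD-1. Il1r1 is a leading gene of mesothelial cluster 6, and mesothelial nuclei were 9.01 against 4.58% and 12.4 against 4.61% in these KPC-4545 pairs. Cell mixture is thus not excluded, although Il1r1 was higher in fibroblast nuclei too. Intervals cover counting error alone. Of the 20 lists, 3 passed in no comparison: regulatory T genes (smallest adjusted p = 0.529, KPC-4545 T nuclei with anti-PD-1, 2 of 3 raised, median 0.02), EMT genes (0.0858, all nuclei with anti-PD-1, 4 of 14 raised, median -0.23) and squamous/basal-type genes (0.382, all nuclei with TGFB-TRAP, 1 of 7 raised, median -0.59). Over all 369 list tests, 73 passed with the preset correlation and 0 with an estimated one.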

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

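The tests on cytoplasmic RNA, on the intron trend in T nuclei, on macrophage nuclei among fibroblasts, on empty droplets for the genes that fell there and on the 7 genes that also rose in empty droplets were chosen after the result was seen. Of 58 groups of 6 libraries checked, 10 had a library far from the other libraries of its line, where chance gives about 1 in 20 groups. In KPC-3403 TGFB-TRAP, epithelial nuclei were 25.1462% and mesothelial nuclei 15.9844%, pericyte/smooth muscle nuclei 8.3821% and B nuclei 0.9747%. In KPC-4545 anti-PD-1, acinar nuclei were 4.0748% and endocrine nuclei 1.2692%. Acinar nuclei were 0.0842% of KPC-3403 anti-PD-1 and dendritic nuclei 0.1294% of KPC-3403 anti-IL-1B, each 1 nucleus against 0 in the other 5 libraries of the line, where any nucleus stands apart by construction, so 8 of the 10 remain to be set against chance. Endothelial nuclei were 4.1511% of KPC-4545 TGFB-TRAP and erythroid nuclei 49.3462% of KPC-4545 anti-PD-1 with anti-IL-1B. By interaction tests, effects differed between groups for 18 genes over all nuclei, 50 in epithelial nuclei and 3 in fibroblast nuclei (TGFB-TRAP with and without anti-PD-1), and for 1 in epithelial nuclei (anti-PD-1 between lines). Outside the classes compared, unnamed clusters 27 and 28 held 7.638 and 7.472% of KPC-4545 TGFB-TRAP, and an unnamed part of cluster 15 held 4.0936% of KPC-3403 TGFB-TRAP. Albumin (Alb) stood at 294.02 CPM over all barcodes of KPC-4545 TGFB-TRAP.

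Genes with long introns were lower in the KPC-3403 epithelial nuclei. The median log2 difference over genes of span at least 50 times their exons stood at -5.051 relative to that of genes at most 2 times. Thinned to equal sums it was -5.19, but thinning keeps proportions, so it cannot decide on depth. The ratio of mitochondrial to Malat1 UMIs was higher in KPC-3403 in 0 of 6 pairs, which argues against more cytoplasmic RNA. In fibroblast nuclei the medians at these spans were -3.46 and 1.41, which argues against a cause in epithelial nuclei alone. Fewer intron UMIs in KPC-3403, through library preparation or intron counting, stay a candidate. Other biological causes stay open, as line and such a step cannot be separated.

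Matrix and epithelial transcripts were lower in KPC-4545 T nuclei with anti-PD-1. Over the 245 genes that fell, the median was -1.597, and -1.273 with the intron trend removed, when 87 still fell, which argues against that trend as the whole cause. The collagen and matrix list had a median of -0.998 over the 5 members left after thinning and -1.146 without, which again cannot decide on depth. Less free RNA from other cells cannot be told apart from a change in the T cells: the markers lay lower relative to empty droplets in 2 of 3 pairs, at 39.5 against 64.6%, 31.4 against 60.3% and 51.7 against 44.6%. Empty medians were 5, 5 and 372 UMIs without anti-PD-1 against 232, 148 and 185 with it, so the count of pairs cannot decide. Depth and a biological effect of anti-PD-1 stay open.

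In fibroblast nuclei with TGFB-TRAP, the 55 genes that rose had a median of 1.638, against 0.278 between empty droplets, which argues against free RNA for the set as a whole. For 7 of them (Igkc, Ighm, Retnla, Pdzd2, Pou2f2, Cacna1d and Prex1) the difference between empty droplets was at least 0.5 times that in the nuclei, with a median of 1.481 against 1.912. These genes had a median of 1.709 in macrophage nuclei, so free RNA may account for their rise, although Pou2f2, Cacna1d and Prex1 stood at 0.087, 0.37 and -0.188 there. Macrophage nuclei among the fibroblasts cannot be told apart from a change in fibroblasts: macrophage markers had a median of 0.629, raised in 11 of 12, while the abundant C1qa, C1qc and Lyz2 stood at 0.20, -0.25 and 0.16. For the 24 genes that fell, the median was -1.402, against -0.374 between empty droplets, and for the 19 also tested in macrophages it was -1.393 in fibroblasts and -1.099 in macrophages. The former is under 0.5 times the fall and the latter above, so free RNA cannot be told apart from other causes for these genes. Has2 fell by 1.10 in both nuclei and empty droplets. Tnc fell in fibroblasts by 2.19 and stood at -0.72 in macrophages, and Nav3 fell by 1.70 and stood at 0.67. An effect of TGF-beta depletion on fibroblasts stays open.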

How the results depend on the processing

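Leaving out 1 library at a time, all barcodes summed, removed or added clusters, the KPC-4545 libraries alone, the libraries of over 100 nuclei and the 2 settings on gene structure are among the alternatives run. Of these, those on clusters, barcodes, small libraries, KPC-4545 alone and gene structure were chosen after the data were seen, and the others were planned. For counts and summaries, 178 values with 1 library left out and 235 under other settings stayed within 1.5 times the reported value, while 126 and 148 moved further. For single genes and classes, 13350 values with 1 library left out kept their side of the threshold, 281 came past it and 398 no longer passed. A further 1, past the threshold as reported, reversed. Under the other settings 15694 kept their side, 284 came past it, 482 no longer passed and 28, past it as reported, reversed. Values that kept their side need not have kept their direction. Of 29534 values of named genes in all settings, 619 from genes not past the threshold changed sign. Except where a setting tests fewer genes, counts or libraries by construction, the cause was not tested.

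Numbers of genes past the threshold follow for each setting that moved them by more than 1.5 times. Thinning to the smallest sum gave 1795, 1695 and 1333 for the lines in all, epithelial and fibroblast nuclei. For the interaction of TGFB-TRAP with anti-PD-1 it gave 0, 3 and 0 there. In epithelial nuclei it gave 0 for anti-PD-1 and 0 for its interaction with line. In fibroblast nuclei it gave 14 for TGFB-TRAP, 1 for anti-IL-1B and 19 for anti-PD-1. For anti-PD-1 it gave 105, 48 and 9 in KPC-4545 macrophage, T and endothelial nuclei. In KPC-4545 macrophage and T nuclei it gave 0 and 1 for TGFB-TRAP, and 0 for anti-IL-1B in T nuclei. Removing the trend over span and exons gave 4224, 3763 and 735 for the lines in all, epithelial and fibroblast nuclei. For anti-PD-1 it gave 1 in all and 47 in fibroblast nuclei. In KPC-4545 it gave 0, 105 and 1 for anti-PD-1 in macrophage, T and endothelial nuclei, and 3 for TGFB-TRAP in T nuclei. It reversed Msln to -0.258, Ikzf2 to 0.002, Vim to -0.199 and Diaph3 to 1.521 for the lines in all nuclei. It reversed Igfbp3 to -0.055, H2-Aa to -0.288, Msln to -0.375, Cdh1 to 0.289, Diaph3 to 1.907 and Slit3 to 1.218 for the lines in epithelial nuclei. It reversed Vim to -0.033, Mki67 to -0.022, Diaph3 to 2.068, Slit3 to 0.346 and Jun to -0.107 for the lines in fibroblast nuclei. Keeping genes of span at most 2 times their exons gave 264, 197 and 44 for the lines in all, epithelial and fibroblast nuclei. It reversed Msln to -0.445 and Vim to -0.378 in all nuclei. In epithelial nuclei H2-Aa reversed to -0.294 and Msln to -0.620, and in fibroblast nuclei Vim to -0.050.

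DESeq2 gave 66 for TGFB-TRAP, 19 for anti-PD-1, 1 for the interaction of TGFB-TRAP with line, 7 for the interaction of anti-PD-1 with line and 2 for the interaction of TGFB-TRAP with anti-PD-1 in all nuclei. This setting gave 1 for the interaction of anti-IL-1B with line, 4 for the interaction of anti-PD-1 with line and 1 for the interaction of TGFB-TRAP with anti-PD-1 in epithelial nuclei. It found 8 for TGFB-TRAP, 11 for anti-PD-1 and 0 for the interaction of TGFB-TRAP with anti-PD-1 in fibroblast nuclei. It gave 0 for anti-IL-1B and 59 for anti-PD-1 in KPC-4545 T nuclei. This setting gave 4 for anti-PD-1 in KPC-4545 endothelial nuclei. No filter on low counts gave 584 for TGFB-TRAP, 77 for anti-IL-1B, 408 for anti-PD-1, 7 for the interaction of anti-IL-1B with line, 15 for the interaction of anti-PD-1 with line and 71 for the interaction of TGFB-TRAP with anti-PD-1 in all nuclei. This setting gave 75 for TGFB-TRAP, 60 for anti-IL-1B, 207 for anti-PD-1, 1 for the interaction of anti-IL-1B with line, 2 for the interaction of anti-PD-1 with line and 147 for the interaction of TGFB-TRAP with anti-PD-1 in epithelial nuclei. It found 13 for anti-IL-1B and 202 for anti-PD-1 in fibroblast nuclei. It gave 53 for TGFB-TRAP, 8 for anti-IL-1B and 318 for anti-PD-1 in KPC-4545 macrophage nuclei. This setting gave 9 for TGFB-TRAP and 20 for anti-PD-1 in KPC-4545 T nuclei. It found 16 for TGFB-TRAP, 23 for anti-IL-1B and 124 for anti-PD-1 in KPC-4545 endothelial nuclei. OrdMag calls alone gave 1 for TGFB-TRAP and 2 for anti-PD-1 in all nuclei. This setting gave 50 for TGFB-TRAP, 12 for anti-PD-1 and 0 for the interaction of TGFB-TRAP with anti-PD-1 in fibroblast nuclei. It found 1 for anti-PD-1 in KPC-4545 macrophage nuclei. Averaging over lines in the interaction design gave 16 for TGFB-TRAP and 26 for anti-PD-1 in all nuclei. This setting gave 1 for anti-IL-1B and 33 for anti-PD-1 in epithelial nuclei. Leaving out clusters 0, 27, 28 and 31 gave 2 for TGFB-TRAP in all nuclei.

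A minimum of 1000 UMIs per nucleus gave 17 for anti-PD-1 in all and 22 in epithelial nuclei. For anti-PD-1 in KPC-4545 it gave 117 in macrophage and 33 in endothelial nuclei. For TGFB-TRAP it gave 1 in KPC-4545 macrophage and 3 in KPC-4545 T nuclei. For anti-IL-1B it gave 6 in fibroblast and 1 in KPC-4545 T nuclei. A filter of at least 20 counts in at least 6 libraries gave 0 for the interaction of TGFB-TRAP with anti-PD-1 in all nuclei. This setting gave 0 for anti-PD-1, 0 for the interaction of anti-PD-1 with line and 10 for the interaction of TGFB-TRAP with anti-PD-1 in epithelial nuclei. It found 956 for the lines, 30 for TGFB-TRAP, 43 for anti-PD-1 and 0 for the interaction of TGFB-TRAP with anti-PD-1 in fibroblast nuclei. It gave 0 for TGFB-TRAP and 0 for anti-PD-1 in KPC-4545 macrophage nuclei. This setting gave 2 for TGFB-TRAP, 0 for anti-IL-1B and 7 for anti-PD-1 in KPC-4545 T nuclei. It found 5 for TGFB-TRAP and 17 for anti-PD-1 in KPC-4545 endothelial nuclei. Leaving out genes below their level in empty droplets gave 4696 for the lines, 5 for anti-PD-1, 0 for the interaction of anti-PD-1 with line and 79 for the interaction of TGFB-TRAP with anti-PD-1 in epithelial nuclei. This setting gave 1537 for the lines, 47 for TGFB-TRAP, 3 for anti-IL-1B and 23 for anti-PD-1 in fibroblast nuclei. It found 1 for TGFB-TRAP and 0 for anti-PD-1 in KPC-4545 macrophage nuclei. It gave 15 for anti-PD-1 in KPC-4545 T nuclei. This setting gave 1 for anti-PD-1 in KPC-4545 endothelial nuclei. Adding unnamed clusters 1, 3, 7, 11 and 21 gave 2 for TGFB-TRAP, 1 for anti-IL-1B and 21 for anti-PD-1 in epithelial nuclei. Fitting KPC-4545 alone gave 0 for anti-PD-1 in epithelial nuclei. This setting gave 2 for anti-IL-1B in fibroblast nuclei. Leaving out the libraries of under 100 nuclei gave 3 for anti-PD-1 in epithelial nuclei. Median-of-ratios size factors gave 0 for the interaction of anti-PD-1 with line and 95 for the interaction of TGFB-TRAP with anti-PD-1 in epithelial nuclei. This setting gave 1 for anti-IL-1B in fibroblast nuclei. It found 1 for anti-PD-1 in KPC-4545 endothelial nuclei. Adding unnamed cluster 10 gave 10 for TGFB-TRAP, 2 for anti-IL-1B and 155 for anti-PD-1 in fibroblast nuclei. Adding the mesothelial cluster 6 gave 25 for TGFB-TRAP, 4 for anti-IL-1B and 153 for anti-PD-1 in fibroblast nuclei. There it reversed Pkhd1l1 to -0.695, Pdgfra to -0.030 and Saa3 to -0.066 for the lines. C3 reversed to -0.236 for TGFB-TRAP and Chrm3 to -0.344 for anti-PD-1. Keeping doublets gave 1 for TGFB-TRAP in KPC-4545 T nuclei. Summing all barcodes reversed Msln to -0.179, C1s1 to -0.025 and C1ra to -0.294 for the lines in all nuclei. With an estimated correlation 0 lists passed in each of the 17 comparisons with a list past the threshold. EdgeR on counts of nuclei put 9 classes past the threshold for the lines, 1 for anti-IL-1B and 1 for anti-PD-1.

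With each library left out in turn, counts ran in all nuclei from 5967 to 8269 for the lines, 0 to 128 for TGFB-TRAP, 0 to 9 for anti-IL-1B and 0 to 66 for anti-PD-1. The range in all nuclei was 0 to 0 for the interaction of TGFB-TRAP with line, 0 to 7 for the interaction of anti-IL-1B with line, 0 to 9 for the interaction of anti-PD-1 with line and 0 to 239 for the interaction of TGFB-TRAP with anti-PD-1. They ran in epithelial nuclei from 5073 to 7322 for the lines, 0 to 12 for TGFB-TRAP, 0 to 2 for anti-IL-1B and 5 to 124 for anti-PD-1. The range in epithelial nuclei was 0 to 3 for the interaction of TGFB-TRAP with line, 0 to 16 for the interaction of anti-IL-1B with line, 0 to 6 for the interaction of anti-PD-1 with line and 0 to 149 for the interaction of TGFB-TRAP with anti-PD-1. They ran in fibroblast nuclei from 1777 to 2675 for the lines, 2 to 106 for TGFB-TRAP, 0 to 7 for anti-IL-1B and 4 to 137 for anti-PD-1. The range in fibroblast nuclei was 0 to 3 for the interaction of TGFB-TRAP with anti-PD-1. They ran in KPC-4545 macrophage nuclei from 0 to 324 for TGFB-TRAP, 0 to 33 for anti-IL-1B and 0 to 559 for anti-PD-1. The range in KPC-4545 T nuclei was 0 to 12 for TGFB-TRAP, 0 to 8 for anti-IL-1B and 0 to 337 for anti-PD-1. They ran in KPC-4545 endothelial nuclei from 0 to 109 for TGFB-TRAP, 1 to 46 for anti-IL-1B and 41 to 175 for anti-PD-1. Ctrb1 with anti-IL-1B in KPC-4545 T nuclei ran from -9.06 to 0.11. An arm left with 1 library was taken to vary like the others. On simulated changes of log2 2, between 64.9 and 96.0% were recovered, 0 took the wrong direction and 1 to 22 unchanged genes were called per comparison. Of changes of log2 1 between 8.5 and 49.5% were recovered, so smaller changes can be missed with these libraries.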

Other observations

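The splits of libraries below were planned, apart from those for KPC-4545 alone, which were chosen after the data were seen. For the lines, 1 of 50 splits gave as many genes as the real one over all nuclei (8233, highest other 4673) and in epithelial nuclei (7138, highest other 4371), and 1 of 81 in fibroblasts (2638, highest other 0), so chance is excluded for each. For anti-PD-1 in fibroblasts, 3 of 100 splits gave as many as 101, the real one included, a share under 0.05. Another split called 134, more than the real one, and the real count was 4 without KPC-4545 Control, so chance is not excluded there. For anti-PD-1 in epithelial nuclei, 12 of 50 splits gave at least 9 genes, the highest 74, so chance is not excluded, and why a split called 74 was not tested.

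For TGFB-TRAP the real count by edgeR was 0 in all and epithelial nuclei, matched in 35 of 35 splits, with highest others of 40 and 18. For anti-IL-1B it was 0 in both, matched in 35 of 35, with highest others of 7 and 42. For anti-PD-1 over all nuclei it was 0, matched in 50 of 50, with a highest other of 140. A count of 0 is matched by any split, so these 5 comparisons decide nothing about chance. At an unadjusted p under 0.05 the real counts were 1166, 611, 285, 355 and 1123 (DESeq2 at the adjusted threshold 66, 0, 0, 0 and 19). The splits were too few for a share under 0.05, at 10 each, for TGFB-TRAP in fibroblasts (79, highest other 5), anti-IL-1B in fibroblasts (0 by edgeR, 364 at an unadjusted p under 0.05, DESeq2 0; highest other 2) and anti-PD-1 in KPC-4545 T (259, highest other 3), macrophage (60, highest other 5) and endothelial nuclei (2, highest other 3). As large as the real count were 1, 10, 1, 1 and 4 of these 10.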
